A study of Mus musculus with 6 samples.

How the data were processed

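Total RNA from mouse ovaries was sequenced for 3 wildtype and 3 GalTKO samples. Per the labels' protocols, ovaries were flash frozen, ribosomal RNA was removed with Ribo-Zero Gold, and strand-specific libraries were made with an Illumina TruSeq total RNA kit, so non-polyadenylated transcripts and unspliced RNA are also counted. The authors deposited 1 table of raw counts per Ensembl gene, whole numbers that are not normalized, for 55487 genes and 6 libraries. Per the submitters' processing notes, the tools were cutadapt 1.16, STAR 2.7.6a, featureCounts 1.6.3 and DESeq2 1.30.1 and the genome build was GRCm38; their roles and settings are not given in the sources used here. The annotation release, the strand setting and the handling of reads that match several places are likewise not given in the sources used here. Counting of shared reads decides the values of pseudogenes, multigene families and overlapping genes, and a total RNA library makes the mitochondrial share depend on RNA handling.

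Gene names, types and coordinates were taken from GENCODE M21 on GRCm38 by Ensembl identifier: 55227 of the 55487 identifiers matched, and the 260 others held 0.00307% of counts. Samples were assigned to genotypes from their titles. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom over genes was at least 13.1, so each was kept as 1 replicate. Totals ran from 19232486 to 25729564 counts per library. Intervals and floors given with counts cover counting error only; a count of 0 was taken to allow up to 3 counts, and intervals are at 95%.

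All tests used R 4.3.3. Counts were tested with edgeR 4.0.16: genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 16957, libraries were scaled by TMM, and a robust quasi-likelihood model with genotype as the only term was fitted to all 6 libraries. The common biological coefficient of variation was 17.4%. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed; p-values are two-sided. The SE of a log2 fold change was its size divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes.

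Before the data were examined, 28 gene lists were fixed from textbook knowledge, covering galactose metabolism, stress and survival pathways, follicular and luteal cells, other cell types and RNA handling; of 605 list entries 558 were tested. Lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 28 lists, and again with a correlation estimated from the data, under which none of the 6 lists that passed did so. The loss of all 6 lists cannot be put down to correlation alone. With the estimated setting, camera p also rose for lists whose estimate lay below 0.01. Camera asks whether a list's genes differ from the other genes. The rule for naming genes was fixed at the same time: Galt; the 12 largest rises and the 12 largest falls among changed genes whose groups do not overlap, with a mean of at least 1 CPM in one group and without predicted or clone-named genes; up to 4 members of each list with the smallest p; and up to 6 changed genes within 20 Mb of Galt. Cyp51, Idi1, 5 further macrophage genes, Invs and the mitochondrial ribosomal RNAs were named after their values were seen, to complete a count. Some genes that the rule names are not reported here. Changed genes within 20 Mb of Galt were compared with the rest of the genome by Fisher's exact test.

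The gene test, the list test and the Galt window test were tested on simulated data made from the real means and library sizes. In a simulated comparison of GalTKO and wildtype with 16957 genes, 77% of 100 genes changed 2-fold and 94% of 100 genes changed 4-fold were recovered, and 19 of 190 calls (10%) were false, above the nominal rate. Without planted changes 1 gene and 0 lists passed. The genes planted with 2-fold and 4-fold changes had a mean log2 CPM above 0, so recovery was not tested for genes with fewer counts. Simulated genes varied independently, while the correlation estimated from the data reached 0.706 in the cholesterol list. The simulation therefore does not test the list test under such correlation.

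Alternatives fixed before the data were examined were median-of-ratios and upper-quartile scaling, the DESeq2 1.42.0 Wald test, limma voom with quality weights, no low-count filter, a stricter filter of 1 CPM in 3 libraries, the replicate number as a block, each library left out in turn, an adjusted p of 0.1, and windows of 5 and 10 Mb. A fit on protein-coding genes and a fit with a luteal marker score as covariate were added after seeing the data. Figures and further tests were made in Python 3.11.15 with scipy 1.17.1, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.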

Results

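Gene expression was measured in whole mouse ovaries collected at postnatal day 49. The 6 libraries came from 3 wildtype ovary samples and 3 samples from mice lacking Galt (GalTKO). Galt encodes galactose-1-phosphate uridylyltransferase, the enzyme of the Leloir pathway of galactose breakdown whose loss causes classic galactosemia in humans. From weaning, mice of both genotypes ate a diet with 2.5% galactose, over 4 weeks. The total gene count per library was 24861338, 23714522 and 23685626 in wildtype replicates 1 to 3, and 25729564, 22910143 and 19232486 in GalTKO replicates 1 to 3. The deposited labels name 1 mixed strain background for all 6 samples and give neither litter nor estrous stage. They do not say whether each sample is 1 animal, so p-values measure the spread between these samples.

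The libraries separated by genotype. The first principal component held 47.1% of the variance and placed the wildtype libraries between -41.9 and -31.9 and the GalTKO libraries between 33.5 and 37.9. Pearson correlations across genes, which are not independent replicates, lay between 0.976 and 0.991 within a genotype and between 0.965 and 0.972 across genotypes. The median SD of log2 CPM (counts scaled to library size) over genes was 0.143 in wildtype and 0.201 in GalTKO libraries. Mitochondrially encoded genes took 1.37%, 1.97% and 1.58% of counts in wildtype replicates 1 to 3 and 2.26%, 2.22% and 3.53% in GalTKO replicates 1 to 3.

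Galt itself (ENSMUSG00000036073; GRCm38 chromosome 4, 41755228 to 41758695, plus strand) was nearly absent from the GalTKO ovaries. It reached 17.8, 16.1 and 17.4 CPM in wildtype replicates 1 to 3, and 0.155, 0.259 and 0 CPM in GalTKO replicates 1 to 3. The 0 in GalTKO replicate 3 allows a level of up to 0.156 CPM, counting error only. The sums were 1227 counts in wildtype and 10 in GalTKO libraries, and the log2 fold change was -6.82 ± 0.41 (SE, n = 3 per group; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000153). Without GalTKO replicate 2 it was -7.51.

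The comparison of the genotypes asked which ovarian genes differ when GALT is missing under a galactose diet, with follicular stress and survival as the stated interest of the study. Of 16957 genes tested, 433 changed at an adjusted p under 0.05, 191 higher and 242 lower in GalTKO ovaries. Among them were 347 protein-coding genes and 54 pseudogenes. Changes of at least 4-fold were found for 137 genes, 76 higher and 61 lower, of which 48 were pseudogenes. By contrast, 177 of the 433 changed by less than 2-fold. An unadjusted p under 0.05 was reached by 2898 of the 16957 tested genes, the background for such counts in the gene lists. The 3 values of one genotype lay above those of the other for all 433 changed genes and for 4022 (23.7%) of all tested genes, where chance gives 10%. The number of changed genes moved when a library was left out. It was 181, 165 and 202 without wildtype replicates 1, 2 and 3, and 263, 742 and 322 without GalTKO replicates 1, 2 and 3. Smaller groups have less power, so lower counts and lost calls in such fits need not come from the library left out. Only without GalTKO replicate 2 did the count rise. Of the 263 without GalTKO replicate 1, 137 were higher and 126 lower, the opposite order to that with all libraries. In all 6 fits with a library left out, 132 of the 433 genes stayed past the threshold, 62 higher and 70 lower, 84 of them changed at least 4-fold.

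The largest rises were mostly in genes with almost no reads in wildtype ovaries. H2-Ea-ps, the mouse MHC class II E alpha locus annotated as a polymorphic pseudogene (ENSMUSG00000036322; chromosome 17, 34341959 to 34344645), had no count in the wildtype libraries and 9.04 ± 1.46 CPM (SD, n = 3) in GalTKO libraries, at least 216-fold higher against a floor of 3 counts over the wildtype group. Rprl3, an RNase P RNA-like gene, had 3 counts in wildtype and 968 in GalTKO libraries, a ratio of 339 (95% interval 116 to 1650, counting error only). Hist1h2al rose by 7.05 ± 0.49 (log2, SE), Ptprv by 6.37 ± 0.56, the zinc finger gene Zfp990 by 6.16 ± 0.69, Ugt1a6b by 5.81 ± 0.56 and H2-Q1 by 5.67 ± 0.65. The ribosomal protein pseudogenes Rps2-ps10 and Rps26-ps1 rose from 1.83 ± 0.20 to 85.2 ± 6.62 CPM and from 4.66 ± 0.92 to 119.1 ± 9.35 CPM (SD, n = 3). Adamdec1, Rnase1 and Baalc also rose, by 4.84 ± 0.39, 4.57 ± 0.26 and 4.54 ± 0.88. Single libraries moved several of these values. All 5 wildtype counts of Zfp990 lay in replicate 3, and without that library it was at least 86.3-fold higher against the floor of 3 counts over the group. All 3 wildtype counts of Rprl3 lay in replicate 2, and without it the gene was at least 227-fold higher. Hist1h2al stood at 6.45 and H2-Q1 at 6.85 without wildtype replicate 1. Baalc stood at 3.41 without GalTKO replicate 1 and at 5.14 without wildtype replicate 2. It was no longer past the threshold without wildtype replicate 1, 2 or 3 or GalTKO replicate 3, with adjusted p up to 0.178, nor with no filter on low counts (0.0578) or among protein-coding genes alone (0.0534).

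After Galt, the largest falls were those of Csprs, Rpl15-ps2, Cd5l, Ifi44l, Cadps, Cntnap5a, Rps15a-ps7, B3gnt3, Rps15a-ps6, Nyap2 and Zfp982. Csprs had a wildtype to GalTKO ratio of counts of 56.1 (95% interval 15.2 to 469), and the interferon-induced gene Ifi44l one of 33.9 (11.3 to 167). Cd5l, a secreted macrophage protein, averaged 2.25 ± 0.73 CPM in wildtype and 0.062 ± 0.037 CPM in GalTKO ovaries (SD, n = 3), and Cadps 6.95 ± 1.10 and 0.230 ± 0.174 CPM. Cntnap5a averaged 11.96 ± 6.11 CPM in wildtype and 0.517 ± 0.286 CPM in GalTKO ovaries. Both GalTKO counts of Csprs lay in replicate 3, and without that library it was at least 26.9-fold lower. Without GalTKO replicate 1 the log2 fold changes of Csprs, Rpl15-ps2, Ifi44l and Cadps were -4.96, -4.53, -5.69 and -5.55, against -5.56, -5.18, -4.93 and -4.87 with all libraries. Nyap2 was lower by -3.71 ± 0.60 (log2, SE) and lost its call without wildtype replicate 2 or 3 or GalTKO replicate 1 or 3, with adjusted p up to 0.0764. Pseudogenes and members of the H2 and Zfp families share sequence with near-identical copies, and how the counting treated such reads is not given in the sources used here, so their values are uncertain. Strain differences between the groups could also give such changes. A rise such as that of H2-Ea-ps, without a count in the 3 wildtype libraries, need not be a response to the loss of Galt.

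**Figure D1:**
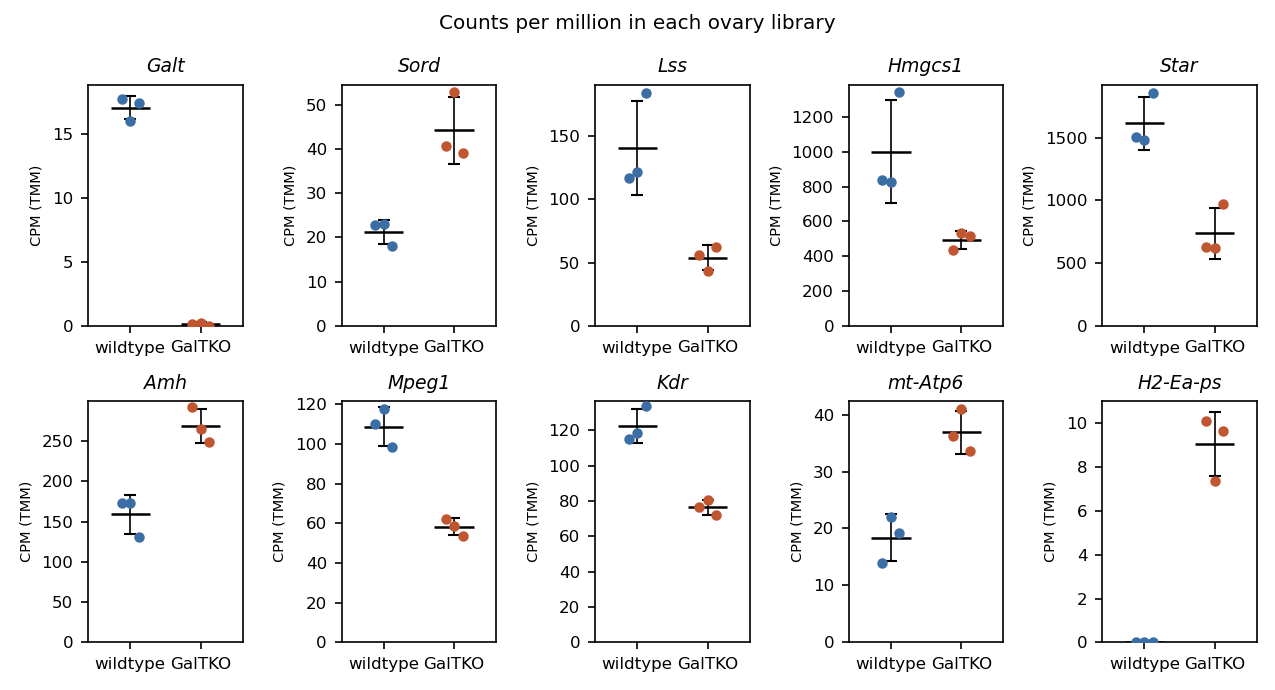
Expression of 10 genes in each library, in CPM on linear axes, with 1 panel per gene; points are the 3 wildtype and 3 GalTKO libraries, and bars give the mean ± SD. Galt lies between 16.1 and 17.8 CPM in wildtype and at or below 0.259 CPM in GalTKO libraries, and H2-Ea-ps has counts in the GalTKO libraries alone.

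Genes of cholesterol synthesis and uptake were lower in GalTKO ovaries. All 24 tested members had a negative log2 fold change, with a median of -0.97, a fold of 0.512. Past the threshold over all genes were 6 members, all lower: Lss, Dhcr7, Insig1, Hmgcs1, Cyp51 and Idi1. The count was 23 when adjusted over the list alone. DESeq2 called 20 members, while 3 passed with no filter on low counts and 3 among protein-coding genes alone. Lss, lanosterol synthase (ENSMUSG00000033105; chromosome 10, 76531588 to 76557138), averaged 140.4 ± 37.5 CPM in wildtype and 53.9 ± 9.75 CPM in GalTKO ovaries (SD, n = 3; log2 fold change -1.38 ± 0.21, SE; edgeR adjusted p = 0.023). Hmgcs1, which makes the HMG-CoA used for mevalonate, averaged 1001 ± 294 and 493 ± 51.9 CPM, and Dhcr7, the last enzyme toward cholesterol in one branch of the pathway, 316 ± 76.6 and 145.5 ± 25.3 CPM. Insig1, which retains the SREBP regulators in the endoplasmic reticulum, changed by -1.22 ± 0.22. The list passed the camera test (adjusted p = 9.32e-22) with a preset correlation between members of 0.01, but not with an estimated correlation (adjusted p = 0.42). The list median was -0.731 without wildtype replicate 3 and from -1.074 to -0.823 with another library left out. Wildtype replicate 3 held 1341 CPM of Hmgcs1 against 839.3 and 823.9 in replicates 1 and 2. The 6 single-gene calls became 1 without wildtype replicate 1, 3 without wildtype replicate 2, 4 without wildtype replicate 3, 0 without GalTKO replicate 1 and 2 without GalTKO replicate 3. The adjusted p of Lss, Dhcr7, Insig1 and Hmgcs1 reached 0.0768, 0.108, 0.129 and 0.13 in such fits, and 0.0554, 0.0659, 0.117 and 0.0724 with no filter on low counts. Hmgcs1 reached 0.0557 among protein-coding genes alone, and Insig1 0.0616 with a luteal marker score in the fit.

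Luteal genes were lower as a list, and 1 steroidogenic gene passed by itself with all libraries. Star, the protein that carries cholesterol into mitochondria for steroid synthesis (ENSMUSG00000031574; chromosome 8, 25806555 to 25815982), fell from 1614 ± 212 to 737 ± 200 CPM (SD, n = 3; log2 fold change -1.13 ± 0.19, SE; edgeR adjusted p = 0.0263). It was the single member past the threshold among 19 tested genes of the corpus luteum list and among 18 of the theca and steroidogenic interstitial list, since both hold Star, Cyp11a1 and Hsd3b1. Adjusted over the list alone, 5 luteal genes and 1 theca gene were lower. The HDL receptor gene Scarb1 had a log2 fold change of -1.12 ± 0.23 (adjusted p = 0.0544), Prlr -0.92 ± 0.25 and Cyp11a1 -0.69 ± 0.21, none past the threshold over all genes with all libraries. Scarb1 passed without GalTKO replicate 2 (-0.92, adjusted p = 0.0344) and without GalTKO replicate 3 (-1.34, adjusted p = 0.0406). Hsd3b1 and Fdx1 stood at -0.60 ± 0.23 and -0.53 ± 0.20. The luteal list had a median of -0.37 and passed camera (adjusted p = 0.00371; adjusted p = 0.306 with an estimated correlation). The estimated correlation of the luteal list was -0.00023, below the preset 0.01. A higher correlation between members therefore does not account for its larger p, so the estimated version of the test differs in more than the correlation. Unadjusted camera p went from 0.000795 to 0.0219 for the luteal list. For the theca list, with an estimated correlation of -0.00358, it went from 0.0535 to 0.105. The theca list, with a median of -0.12, did not pass camera (adjusted p = 0.15), although it passed with no filter on low counts (adjusted p = 0.0286). GalTKO replicate 2 stood apart for the theca androgen enzyme gene Cyp17a1, chosen after its values were seen, at 7.29 CPM against 399.7 and 296.0 in GalTKO replicates 1 and 3 and 119.6, 132.1 and 119.2 in wildtype. Without that library 1 theca gene was higher and 2 were lower, and the theca median was -0.199. It was -0.010 without wildtype replicate 1 and -0.033 without GalTKO replicate 3. The luteal median was -0.58 without GalTKO replicate 2 and -0.59 under limma voom, and 3 of its genes passed without GalTKO replicate 2. DESeq2 called 5 luteal and 2 theca genes, and voom 2 luteal genes. With a luteal marker score in the fit 3 luteal and 2 theca genes passed. Star lost its call without wildtype replicate 1, 2 or 3 or GalTKO replicate 1, with adjusted p up to 0.0906.

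Granulosa genes changed in both directions, without a shift of the follicle lists. Of 23 granulosa cell genes, 2 rose, 1 fell and 20 did not pass. The counts were 3 higher and 4 lower when adjusted over the list alone. In edgeR 11 of the 23 had an unadjusted p under 0.05, against 2898 of all 16957 tested genes. DESeq2 called 6 granulosa genes, and 7 passed with no filter on low counts. Amh, the hormone of growing follicles (ENSMUSG00000035262; chromosome 10, 80805243 to 80807648), rose from 159 ± 24.3 to 268.8 ± 21.4 CPM (SD, n = 3; log2 fold change 0.76 ± 0.13, SE; edgeR adjusted p = 0.0214). Slc18a2 rose by 0.77 ± 0.14, and Nr5a2, a nuclear receptor needed for ovulation and luteal function, was lower by -0.64 ± 0.13. Nppc stood at -0.78 ± 0.18 (adjusted p = 0.0693). Nppc passed without GalTKO replicate 1 (-0.96, adjusted p = 0.0454). Without GalTKO replicate 2, 3 granulosa genes were higher and 2 lower. The granulosa list had a median of 0.06 (camera adjusted p = 0.796), or from -0.012 (without GalTKO replicate 1) to 0.144 (without wildtype replicate 1) with a library left out. None of 36 oocyte genes passed in edgeR, where 11 had an unadjusted p under 0.05, against 2 called by DESeq2 and 0 by limma voom. The list median was 0.10 (camera adjusted p = 0.793), with Oosp1 at 0.66 ± 0.18, Uchl1 at -0.87 ± 0.26, Ddx4 at -1.08 ± 0.35 and Sohlh1 at -1.53 ± 0.47. The median was 0.006 without wildtype replicate 3, 0.036 without GalTKO replicate 1 and 0.166 without wildtype replicate 2, and Uchl1 passed without GalTKO replicate 1 (-1.21, adjusted p = 0.0151). None of 12 tested genes of the ovulatory response to luteinizing hormone passed in edgeR, with 2 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by voom. The list median was -0.03 (camera adjusted p = 0.551), with Cited4 at -0.49 ± 0.16, Runx2 at -0.88 ± 0.28, Btc at 0.47 ± 0.35 and Tnfaip6 at 0.88 ± 0.56, or -0.09 without GalTKO replicate 1. Cited4 passed without GalTKO replicate 2 (-0.64, adjusted p = 0.041), and 1 member was higher without GalTKO replicate 1. With no filter on low counts 18 ovulatory genes were tested in edgeR and 2 were higher. The ovulatory median ran from -0.119 (without GalTKO replicate 2) to 0.062 (without wildtype replicate 3). Amh lost its call without wildtype replicate 1 or 2 or GalTKO replicate 1 (adjusted p up to 0.0697). Slc18a2 lost its call without wildtype replicate 1 or 3 or GalTKO replicate 1 (up to 0.12), and Nr5a2 in 5 of 6 such fits, all but that without GalTKO replicate 2 (up to 0.135) and among protein-coding genes alone (0.0539).

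Macrophage and myeloid genes were lower in GalTKO ovaries. Of 25 tested members 23 had a negative log2 fold change, with a median of -0.65. Over all genes 9 passed, all lower: Mpeg1, Ctss, Csf1r, Lyz2, H2-Ab1, C1qb, Cd163, H2-Eb1 and Cd74. The count was 20 when adjusted over the list alone. DESeq2 called 17 members, and 16 passed with no filter on low counts. Mpeg1, a pore-forming protein of phagocytes (ENSMUSG00000046805; chromosome 19, 12460779 to 12465283), fell from 108.6 ± 9.75 to 58.3 ± 4.31 CPM (SD, n = 3; log2 fold change -0.90 ± 0.10, SE; edgeR adjusted p = 0.00307). The lysosomal protease gene Ctss fell from 60.6 ± 8.31 to 27.2 ± 5.21 CPM, the receptor gene Csf1r, on which macrophage survival depends, from 46.9 ± 1.58 to 31.4 ± 2.90 CPM, and Lyz2 from 109.1 ± 9.39 to 69.7 ± 9.14 CPM. The list passed camera (adjusted p = 2.35e-17; adjusted p = 0.276 with an estimated correlation). Without wildtype replicate 1 or 2, 2 members passed, 5 without GalTKO replicate 1, 4 without GalTKO replicate 3 and 6 without wildtype replicate 3. Csf1r and Lyz2 reached adjusted p of 0.112 and 0.122, while Mpeg1 and Ctss passed in all 6 fits.

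Interferon response genes were lower as a list, with 20 of 21 tested members negative and a median of -0.92. One member, Ifi44 (chromosome 3, 151730922 to 151749960), passed over all genes, at 7.60 ± 3.94 CPM in wildtype and 1.48 ± 0.50 CPM in GalTKO ovaries (SD, n = 3), and 2 were lower when adjusted over the list alone. Oas1a had a log2 fold change of -1.45 ± 0.44 (SE) and Ifit2 one of -0.86 ± 0.27, neither past the threshold with all libraries. Ifit2 passed without GalTKO replicate 2 (-1.15, adjusted p = 0.0452). The list passed camera (adjusted p = 5.4e-06; adjusted p = 0.73 with an estimated correlation). Without wildtype replicate 3 its median was -0.53, and without GalTKO replicate 2 the passing members numbered 4. DESeq2 called 5 members, voom called 0, and 3 passed with no filter on low counts and 6 with a luteal marker score in the fit. Ifi44 lost its call without wildtype replicate 2 or 3 or GalTKO replicate 1 or 3, with adjusted p up to 0.135, with voom (0.111) and among protein-coding genes alone (0.0533). Ifi44l, among the largest falls, lies near Ifi44 on chromosome 3 (151758737 to 151762892), and a local difference between the groups was not tested.

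Of 12 tested lymphocyte genes 1 passed, the interleukin 7 receptor gene Il7r, lower by -1.87 ± 0.37 (log2, SE; edgeR adjusted p = 0.0425) and likewise the 1 member that passed when adjusted over the list alone. DESeq2 called 2. Cd4, Igkc and Cd3e stood at -1.02 ± 0.31, -0.84 ± 0.38 and -0.84 ± 0.41. The lymphocyte list had a median of -0.53 and did not pass camera (adjusted p = 0.125), although it passed with no filter on low counts, where 18 members were tested (adjusted p = 0.0261). It also passed with a stricter filter, which left 3 members with a median of -1.02 (adjusted p = 0.00542). Its median was -0.214 without wildtype replicate 2 and -0.326 without GalTKO replicate 2. None of 15 inflammatory cytokine and chemokine genes passed in edgeR, with 2 at an unadjusted p under 0.05, 2 called by DESeq2 and 0 by voom. Vcam1, at -0.999 ± 0.227, was lower when adjusted over the list alone, and Cxcl10, Saa3 and Ccl5 stood at -2.19 ± 0.78, -1.78 ± 0.81 and 0.75 ± 0.46. That list had a median of 0.002, a mean of -0.34 and a camera direction toward lower values (adjusted p = 0.369). Its median was -0.496 without GalTKO replicate 1, -0.189 without wildtype replicate 3 and 0.121 without wildtype replicate 2. Wildtype replicate 3 held 5.15 CPM of Cxcl10 against 0.92 and 1.48 in replicates 1 and 2, and without it Cxcl10 stood at -1.13 and Saa3 at -1.14. Saa3 stood at -2.41 without GalTKO replicate 3, and Vcam1 passed without GalTKO replicate 1 (-1.23, adjusted p = 0.043). Il7r lost its call in 5 of 6 fits with a library left out, all but that without GalTKO replicate 2 (adjusted p up to 0.155), and among protein-coding genes alone (0.0534).

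Endothelial genes were lower, 17 of 18 by sign, with a median of -0.39. The VEGF receptor genes Kdr and Flt1 and the adhesion gene Pecam1 fell, and 14 members were lower when adjusted over the list alone. Kdr (ENSMUSG00000062960; chromosome 5, 75932827 to 75978458) averaged 122.3 ± 9.81 CPM in wildtype and 76.3 ± 4.37 CPM in GalTKO ovaries (SD, n = 3; log2 fold change -0.68 ± 0.09, SE; edgeR adjusted p = 0.00769). Flt1 changed by -0.55 ± 0.09 and Pecam1 by -0.60 ± 0.12, and Tie1 stood at -0.40 ± 0.09 (adjusted p = 0.0649). DESeq2 called 8 members, and 7 passed with no filter on low counts and 6 with a luteal marker score in the fit. The list passed camera (adjusted p = 9.14e-08; adjusted p = 0.42 with an estimated correlation). Kdr kept its call in all 6 fits with a library left out. Flt1 lost it without wildtype replicate 1, 2 or 3 or GalTKO replicate 3 (adjusted p up to 0.113) and Pecam1 in 5 of 6, all but that without wildtype replicate 1 (up to 0.142), as well as with upper-quartile scaling (0.0501), voom (0.057) and protein-coding genes alone (0.058). The 3 calls became 1 without wildtype replicate 2 or 3 or GalTKO replicate 3, and 6 without GalTKO replicate 2.

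Of 14 smooth muscle and pericyte genes 1 passed, also over the list alone: the pericyte gene Rgs5 was lower by -0.72 ± 0.10 (log2, SE; edgeR adjusted p = 0.0098), with Notch3 at -0.35 ± 0.11, Mcam at -0.40 ± 0.16 and Smtn at 0.23 ± 0.10. That list had a median of 0.11, a mean of -0.03 and a camera direction toward lower values (adjusted p = 0.551), with 8 members positive and 6 negative. Its median was -0.16 without GalTKO replicate 2 and 0.283 without GalTKO replicate 3. Of 14 ovarian surface epithelium genes the keratin gene Krt8 rose by 0.60 ± 0.12 (adjusted p = 0.044), and Epcam, Krt18 and Krt7, at 1.02 ± 0.25, 0.92 ± 0.23 and 1.03 ± 0.27, brought the count adjusted over the list alone to 4 higher. The epithelium list, with a median of 0.15, did not pass camera (adjusted p = 0.0787), but passed without GalTKO replicate 1 (adjusted p = 0.0441), without GalTKO replicate 3 (0.00622), with no filter on low counts (0.0261), among protein-coding genes alone (0.0289) and with DESeq2 fold changes (0.0413). Its median was 0.344 without GalTKO replicate 3 and 0.277 without wildtype replicate 2. DESeq2 called 4 of its genes, and Krt7 passed without GalTKO replicate 3 (1.27, adjusted p = 0.0221). Of 7 tested adipocyte genes the lipid droplet gene Plin1 rose by 1.06 ± 0.13, 1 higher and 1 lower (Lipe, -0.62 ± 0.13) passed over the list alone. DESeq2 and voom each called 2 adipocyte genes. Acvr1c and Pparg stood at 0.99 ± 0.38 and -0.57 ± 0.29. The adipocyte median of -0.08 and mean of -0.005 were negative and the camera direction positive (adjusted p = 0.831). The median was 0.105 without GalTKO replicate 1 and -0.29 without GalTKO replicate 2, where Lipe also passed (-0.76, adjusted p = 0.0127). Rgs5 lost its call without wildtype replicate 2 (adjusted p = 0.0552), and Krt8 in 5 of 6 fits with a library left out, all but that without GalTKO replicate 2 (up to 0.165), and among protein-coding genes alone (0.0505).

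Oviduct and erythroid genes, markers of neighbouring tissue and of blood, had no member past the threshold in edgeR among 7 and 4 tested. Unadjusted p under 0.05 was reached by 2 oviduct genes and 1 erythroid gene. DESeq2 called 2 and 1, and voom 0 in both lists. The oviduct median was -0.11 (camera adjusted p = 0.974), or from -0.287 (without wildtype replicate 1) to 0.084 (without wildtype replicate 2), and 1 gene was higher and 1 lower over the list alone (Prom1 at 1.48 ± 0.42 and Dnah9 at -0.95 ± 0.30), and Rsph1 stood at 0.90 ± 0.41. The secretory gene Ovgp1 had 20.3 CPM in wildtype replicate 2 and at most 0.80 CPM in the other wildtype libraries. The erythroid median was -0.63 (camera adjusted p = 0.254), with Alas2 (-1.55 ± 0.44) the 1 gene lower over the list alone, and Epb42 and Hbb-bs at -0.75 ± 0.59 and -0.50 ± 0.56. Alas2 passed without GalTKO replicate 2 (-2.18, adjusted p = 0.0242), as did Prom1 (1.80, adjusted p = 0.0223), and Epb42 stood at -1.46 without GalTKO replicate 1. The erythroid list passed without wildtype replicate 1 (median -1.02, adjusted p = 0.0301), and its median was -0.361 without wildtype replicate 3 and -0.406 without wildtype replicate 2.

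With all libraries and the default filter, the stress and survival lists that the study's title points to did not pass camera on edgeR values. In that fit edgeR called 1 of their genes. Counts at an unadjusted p under 0.05 in these lists stand against 2898 of all 16957 tested genes. The unfolded protein response, signalling and heat shock lists passed under other settings, given with each list. DESeq2 called up to 4 genes in a list, voom up to 1, and edgeR with no filter on low counts up to 3. Tnfrsf10b, a death receptor for TRAIL and a p53 target (ENSMUSG00000022074; chromosome 14, 69767472 to 69784411), rose from 18.9 ± 1.02 to 35.4 ± 4.00 CPM (SD, n = 3; log2 fold change 0.90 ± 0.11, SE; edgeR adjusted p = 0.0059), the 1 of 26 genes of p53 targets and apoptosis to pass, also over the list alone. DESeq2 called 2. Cdkn1a stood at 1.32 ± 0.49, with 22.3 ± 2.14 CPM in wildtype and 55.3 ± 39.0 CPM in GalTKO ovaries. GalTKO replicate 1 held 100.1 CPM of Cdkn1a against 29.3 and 36.6 in replicates 2 and 3, and without it the log2 fold change was 0.56. Phlda3 and Pmaip1 stood at -0.71 ± 0.19 and -0.66 ± 0.32, and Phlda3 passed without GalTKO replicate 1 (-0.95, adjusted p = 0.0328). The p53 list had a median of -0.07, a mean of 0 and a camera direction toward lower values (adjusted p = 0.831). Chromosome 14, which holds Tnfrsf10b, had an excess of changed genes (28 of 563, Fisher's exact test, adjusted p = 0.00897 over chromosomes). Adamdec1, among the largest rises, lies near Tnfrsf10b (68563380 to 68582095), and a local difference between the groups was not tested.

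None of 23 genes of the unfolded protein response passed in edgeR, with 3 at an unadjusted p under 0.05 and 0 called by DESeq2 or voom. Sec61b, Creld2, Dnajb11 and Pdia6 stood at 0.31 ± 0.10, 0.53 ± 0.18, 0.32 ± 0.13 and 0.30 ± 0.15 (log2, SE). The list median was 0.13 (camera adjusted p = 0.27), and the list passed with voom (adjusted p = 0.0381) and without GalTKO replicate 2 (median 0.22, adjusted p = 0.0446). Its median was -0.004 without GalTKO replicate 1 and 0.061 without wildtype replicate 3. None of 24 integrated stress response genes passed in edgeR, with 5 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by voom. The list median was 0.10 (camera adjusted p = 0.551), with Mthfd2 at -0.51 ± 0.15, Eif2ak4 at 0.33 ± 0.10, Psat1 at 0.48 ± 0.17 and Sesn2 at 0.47 ± 0.18. Mthfd2 passed without GalTKO replicate 1 (-0.69, adjusted p = 0.0337) and Psat1 without GalTKO replicate 2 (0.63, adjusted p = 0.0464). The list median was 0.179 without GalTKO replicate 2.

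None of 25 antioxidant and NRF2 genes passed in edgeR, with 6 at an unadjusted p under 0.05, 3 called by DESeq2 and 0 by voom. Still, 2 were lower over the list alone, the peroxide-reducing enzyme gene Prdx6 at -0.76 ± 0.17 and the mitochondrial superoxide dismutase gene Sod2 at -0.44 ± 0.11 (log2, SE). Gsta2 and Prdx1 stood at -0.75 ± 0.21 and -0.28 ± 0.10, and the list median was -0.07 (camera adjusted p = 0.261), or 0.015 without wildtype replicate 3. Prdx6 passed without GalTKO replicate 3 (-0.93, adjusted p = 0.0391), and 1 antioxidant gene was higher without GalTKO replicate 2. With no filter on low counts 3 antioxidant genes were lower in edgeR. Of 33 genes of PI3K, AKT, FOXO and mTOR signalling none passed in edgeR, with 7 at an unadjusted p under 0.05, 4 called by DESeq2 and 1 by voom. Lower over the list alone were 3 genes, Insr at -0.42 ± 0.09 (adjusted p over all genes 0.0505), Inpp5d at -0.54 ± 0.13 and Cdkn1b at -0.71 ± 0.18, while Gsk3b stood at -0.28 ± 0.08. The signalling list had a median of -0.06 and did not pass camera (adjusted p = 0.15), although it passed with voom (0.0335) and with no filter on low counts (0.0292), where 3 members were lower. Its median was -0.122 without GalTKO replicate 2, where 1 member was lower, -0.108 without GalTKO replicate 1 and -0.033 without wildtype replicate 1. None of 16 heat shock genes passed in edgeR, with 4 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by voom. The list median was -0.13 (camera adjusted p = 0.514), with Hspa1a at -0.85 ± 0.26, Cryab at 0.47 ± 0.16, Hspa4l at -0.21 ± 0.08 and Hspd1 at -0.27 ± 0.11. It passed without GalTKO replicate 1 (median -0.25, adjusted p = 0.0477), while its median was 0.019 without GalTKO replicate 2, -0.043 without wildtype replicate 1 and -0.079 without GalTKO replicate 3.

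In galactose metabolism, Sord rose beside the loss of Galt. Sord, sorbitol dehydrogenase of the polyol pathway (ENSMUSG00000027227; chromosome 2, 122234749 to 122265340), averaged 21.3 ± 2.76 CPM in wildtype and 44.2 ± 7.52 CPM in GalTKO ovaries (SD, n = 3; log2 fold change 1.05 ± 0.15, SE; edgeR adjusted p = 0.0109), and passed in all 6 fits with a library left out. Of 17 tested genes 15 did not pass. Over the list alone 1 was higher and 2 were lower, Galt among them. Pgm3 stood at 0.39 ± 0.12. The list had a median of 0.05, a mean of -0.35 that includes Galt, and a camera direction toward lower values (adjusted p = 0.207). Its median was -0.028 without GalTKO replicate 2, 0.018 without wildtype replicate 2 and 0.101 without GalTKO replicate 3. None of 42 genes of N-glycosylation and sugar nucleotides passed in edgeR, with 3 at an unadjusted p under 0.05 and 0 called by DESeq2 or voom. The median was -0.008, the mean 0.001 and the camera direction toward lower values (adjusted p = 0.895). The N-glycosylation median ran from -0.031 (without wildtype replicate 2) to 0.021 (without wildtype replicate 3). Gmppa, Man1a, Alg2 and Mpi stood at 0.29 ± 0.10, -0.28 ± 0.10, -0.22 ± 0.09 and 0.24 ± 0.11.

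Of 27 tested extracellular matrix and fibrosis genes 1 passed, also over the list alone: Loxl2, a collagen-crosslinking oxidase, rose by 0.67 ± 0.12 (log2, SE; edgeR adjusted p = 0.0286). Mmp2, Postn and Mmp14 stood at -0.35 ± 0.16, -0.48 ± 0.23 and 0.20 ± 0.12, and the list had a median of -0.007, a mean of 0.05 and a camera direction toward lower values (adjusted p = 0.895). With a library left out the median ran from -0.168 (without GalTKO replicate 2) to 0.122 (without GalTKO replicate 3). Without GalTKO replicate 3, 2 members were higher. Among 29 cell division genes the cyclin gene Ccnd1 was lower by -0.82 ± 0.15, the 1 call over all genes and over the list alone. Cdc20, Mcm5 and Mcm2 stood at 0.40 ± 0.10, 0.26 ± 0.10 and 0.28 ± 0.11 (list median 0.11, camera adjusted p = 0.514). That median was 0.012 without GalTKO replicate 2, 0.039 without wildtype replicate 2 and 0.041 without wildtype replicate 3. Of 22 immediate early genes Ier3 and Egr3 rose by 0.85 ± 0.17 and 1.58 ± 0.33, and over the list alone Dusp1 (-0.97 ± 0.20) was lower as well. Fosl2 stood at -0.23 ± 0.09 (list median 0.03, camera adjusted p = 0.551). The median was 0.003 without wildtype replicate 1, 0.007 without wildtype replicate 3 and 0.053 without wildtype replicate 2 or GalTKO replicate 3. Dusp1 passed over all genes without wildtype replicate 1 (adjusted p = 0.0492) and without GalTKO replicate 2 (0.0192). Loxl2 lost its call without wildtype replicate 1, 2 or 3 (adjusted p up to 0.142), and Ccnd1, Ier3 and Egr3 in 5 of 6 fits, all but that without GalTKO replicate 2 (up to 0.129, 0.166 and 0.176). Among protein-coding genes alone Ier3 and Egr3 reached 0.0501 and 0.0604, and Egr3 0.0553 with a stricter filter. DESeq2 called 2 cell division genes.

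Mitochondrially encoded protein genes were higher in GalTKO ovaries, all 13 by sign, with a median of 0.77. mt-Atp6, a subunit of ATP synthase, rose from 18.4 ± 4.13 to 36.9 ± 3.78 CPM (SD, n = 3; log2 fold change 1.01 ± 0.17, SE; edgeR adjusted p = 0.0233), and 8 members passed over the list alone. DESeq2 called 8, and 4 passed with no filter on low counts. mt-Co2, mt-Atp8 and mt-Nd4l stood at 1.05 ± 0.24, 0.77 ± 0.21 and 0.96 ± 0.27, and the ribosomal RNAs mt-Rnr1 and mt-Rnr2 at 1.26 ± 0.37 and 0.98 ± 0.27, not past the threshold. The list passed camera (adjusted p = 3.04e-07; adjusted p = 0.42 with an estimated correlation). The mitochondrial share of all counts, from 1.37% to 1.97% in wildtype and from 2.22% to 3.53% in GalTKO libraries, moved with it. Its median was 0.48 without GalTKO replicate 3, the library with the highest share, and mt-Atp6 lost its call without wildtype replicate 3 or GalTKO replicate 1 (adjusted p up to 0.0906). The CPM of mt-Atp6 was a small part of the mitochondrial share. How reads that match several places were counted is not given in the sources used here, so its values are uncertain.

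**Figure D2:**
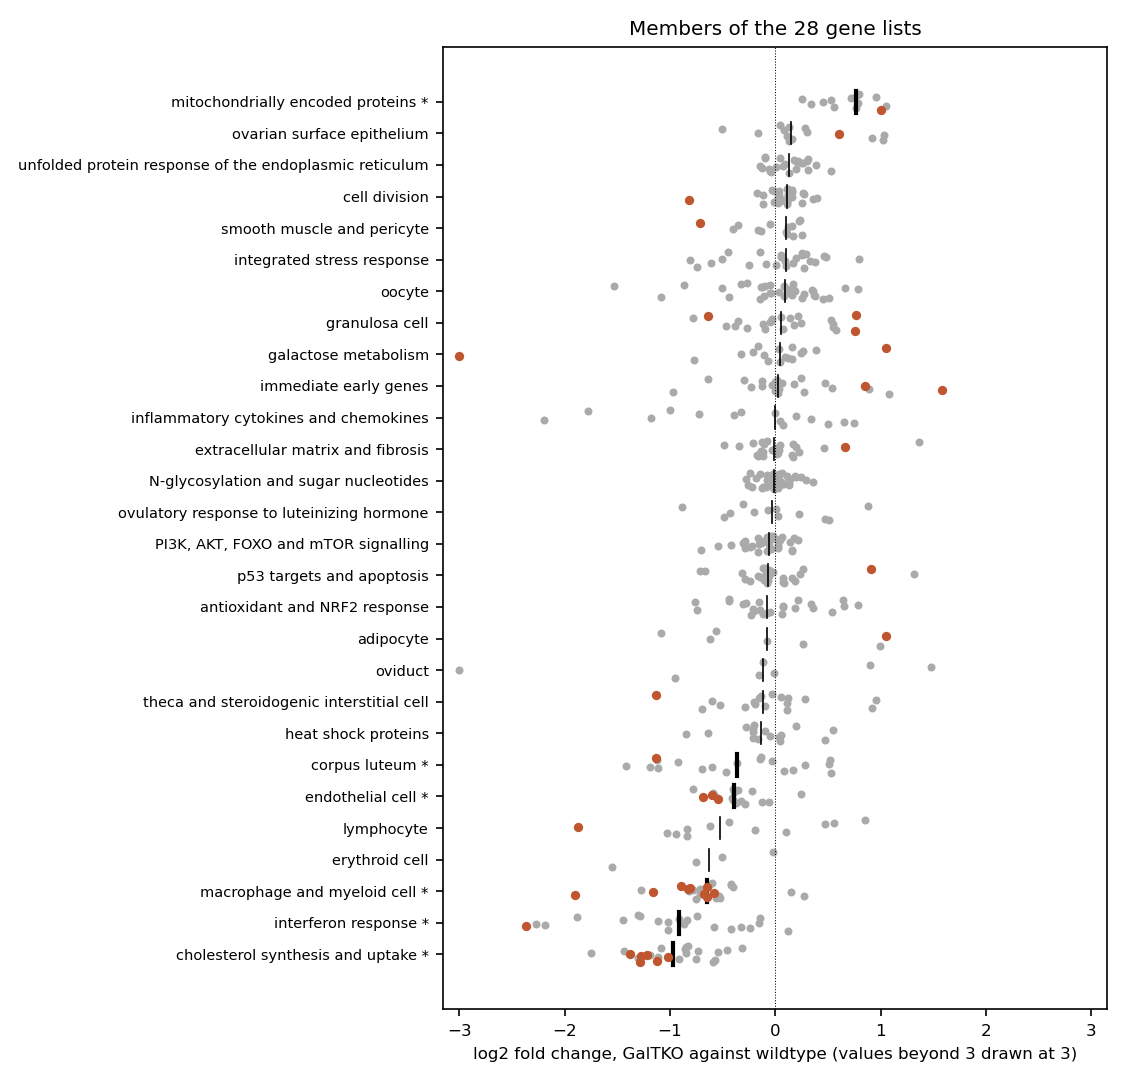
Log2 fold change, GalTKO against wildtype, of each tested member of 28 gene lists (n = 3 libraries per genotype); the black bar is the list median, thick and starred where the camera test passed with the preset correlation, and orange points are genes past an adjusted p of 0.05. Values beyond 3 (Galt, Ovgp1) are drawn at 3; the 6 starred lists have medians from -0.97 for cholesterol synthesis and uptake to 0.77 for mitochondrially encoded proteins.

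Around Galt, where DNA from the strain in which the mutation was made can remain, 7 of 194 tested genes within 20 Mb changed (3.61%), against 423 of 16747 elsewhere (2.53%), with Galt left out. The odds ratio was 1.44 (95% interval 0.569 to 3.06; two-sided Fisher's exact p = 0.35), so an excess was not detected. Among the 7 genes were Gm12751, Gm11942, Tmeff1, Il11ra1 and Invs. The processed pseudogene Gm12751 (34354043 to 34354423) changed by 5.96 ± 0.38 (log2, SE) and Gm11942 (32964888 to 32965232) by -3.80 ± 0.24. Tmeff1 was higher by 0.84 ± 0.13. Il11ra1 was lower by -0.52 ± 0.09; its annotated interval (41699989 to 41769474, plus strand) contains that of Galt, so reads of the 2 genes could be exchanged in counting. The odds ratio was 0.412 within 5 Mb and 0.994 without wildtype replicate 1, and 2.20 without wildtype replicate 2. Tmeff1 and Il11ra1 lost their calls in 2 and 5 of 6 fits with a library left out, with adjusted p up to 0.0729 and 0.134.

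**Figure D3:**
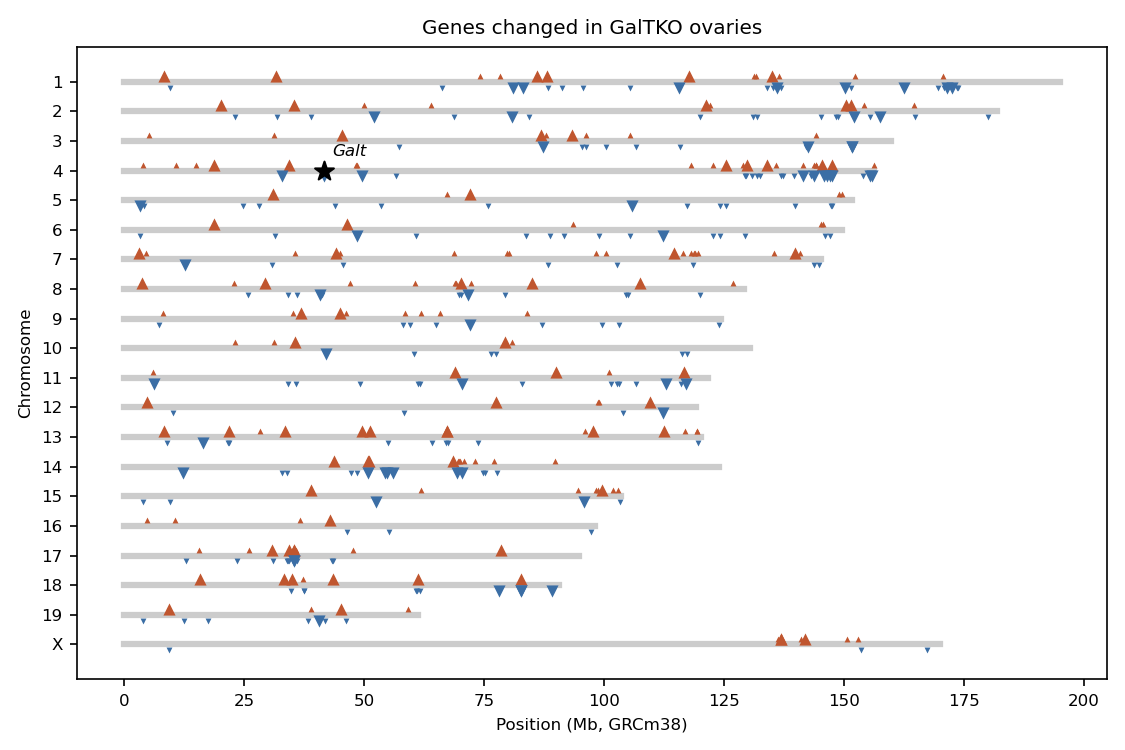
Position in megabases (Mb, GRCm38) of the 433 changed genes that lie on the chromosomes drawn; orange upward triangles are higher and blue downward triangles lower in GalTKO ovaries, large symbols mark changes of at least 4-fold, and the star marks Galt. On chromosome 4 the changed genes gather between 120 and 160 Mb, away from Galt.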

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

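The fits on protein-coding genes and with the luteal score were chosen after the data were seen; the other alternatives were planned. Galt kept its direction and its call under every alternative, with log2 fold changes from -7.51 to -6.35 when single libraries were left out. Against 433 changed genes, the DESeq2 test gave 1049 (432 shared), no low-count filter 877 (412 shared), an adjusted p of 0.1 761, the luteal score 650 (400 shared) and protein-coding genes 264, where fewer genes were tested. Leaving out 1 library gave 165 to 742 genes. The count stayed within 1.5 times with median-of-ratios scaling (426), upper-quartile scaling (400), voom (529) and the stricter filter (388). Other causes were not tested. The labels do not say whether replicate numbers pair the samples. Deviations of same-numbered libraries correlated at 0.0926, -0.0404 and 0.078, and those of differently numbered libraries at -0.118 to 0.029. Such small values neither show nor exclude pairing. With the replicate block 321 genes passed (257 shared), 8 lists passed, Galt stood at -6.84, the window odds ratio was 1.38 and 38.9% of changed genes were higher. Members past the threshold then numbered 14 for cholesterol, 5 for macrophage and 4 for corpus luteum, and the theca and epithelium lists passed (adjusted p = 0.0298 and 0.0338).

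The 6 lists passed under each alternative except the estimated correlation, where 0 passed; 10 passed with no filter, and 6 to 8 with a library left out. The window odds ratio, never past the threshold, was 0.996 with voom, 0.412 within 5 Mb and 0.994 to 2.20 with a library left out; the cause was not tested. Lists that did not pass before or after also changed the direction of their test: extracellular matrix with DESeq2 (median -0.011) and with protein-coding genes (-0.003); N-glycosylation with voom (0.007) and with protein-coding genes (-0.003); adipocyte with voom (-0.22), block (-0.099) and luteal score (-0.206); ovulatory response with no filter (0.117); oviduct with no filter (-0.025), stricter filter (0.399), block (-0.106), protein-coding genes (-0.109) and luteal score (-0.056). With a library left out, medians ran from -0.012 to 0.144 for granulosa, -0.287 to 0.084 for oviduct, 0.006 to 0.166 for oocyte, -0.119 to 0.062 for the ovulatory response, -0.031 to 0.021 for N-glycosylation, -0.004 to 0.218 for the unfolded protein response, 0.069 to 0.179 for the integrated stress response, -0.29 to 0.105 for adipocyte, 0.012 to 0.151 for cell division, -0.086 to -0.047 for p53 targets, -0.168 to 0.122 for extracellular matrix and -0.159 to 0.283 for smooth muscle. Lists whose test kept its direction had medians from -0.251 to 0.019 for heat shock, -0.107 to 0.015 for antioxidant, -0.028 to 0.101 for galactose and -0.496 to 0.121 for cytokines. Tnfaip6 ran from -0.09 to 1.2, not past the threshold. The cause was not tested.

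Of 55 reported genes that the fixed rule named and that were past the threshold, 30 passed in all 6 fits with a library left out. Genes named after their values were seen are not among them. No scaling turned the sign of a changed gene, and the median of all genes moved by at most 0.023 (log2). The share of changed genes that were higher was 44.1%, 43.7% with median-of-ratios and 48.8% with upper-quartile scaling. It ran from 39.2% without wildtype replicate 1 to 52.1% without GalTKO replicate 1. At this depth a 2-fold change was found in 77% of simulated cases, which left out genes with the fewest counts. Smaller changes, and changes in such genes, can be missed.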

Other observations

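The groups in this part, and every test in it except those of other splits and of GC content and length, were chosen after the results were seen. Genes of the major histocompatibility complex changed in both directions. Of 25 tested H2 genes 3 were higher (H2-Ea-ps, H2-Q1, H2-Q2) and 7 lower (H2-D1, H2-K1, H2-Q6, H2-Q7, H2-T24, H2-Ab1, H2-Eb1), with 6 lower under upper-quartile scaling. The class I gene H2-D1 averaged 153.9 CPM in wildtype and 56.8 CPM in GalTKO ovaries (log2 fold change -1.44 ± 0.14, SE, n = 3; edgeR adjusted p = 0.00117), while H2-Q2 averaged 0.083 and 1.14 CPM. On chromosome 17 from 33 to 37 Mb, which holds H2-Ea-ps and H2-Q1, 11 of 143 tested genes changed (7.69%), against 2.51% of the rest. The odds ratio was 3.24 (Fisher's exact p = 0.00112).

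Changed genes also gathered on distal chromosome 4. Chromosome 4 held 49 of 1008 tested genes changed (4.86%, adjusted p = 0.000363 over chromosomes) and chromosome 14 held 28 of 563 (4.97%, adjusted p = 0.00897). From 140 to 160 Mb on chromosome 4, 22 of 199 genes changed, 10 of them at least 4-fold. This stretch holds a zinc finger cluster in which 2 of 12 tested Zfp genes were higher (Zfp990, Zfp985) and 4 lower (Zfp982, Zfp991, Zfp993, Zfp984), or 3 lower under upper-quartile scaling. The oocyte-expressed genes Oog2 and Oog3 there were higher by 1.53 ± 0.25 and 1.07 ± 0.19, and the podoplanin gene Pdpn was lower by -1.19 ± 0.10. One library stood more than 2 log2 units from a close pair in its group for 68 genes in GalTKO and 12 in wildtype ovaries, most often GalTKO replicate 2 (36 genes), among them the theca gene Cyp17a1 and the luteal gene Sfrp4 (175.8 CPM against 1965 and 1699 in GalTKO replicates 1 and 3).

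The 433 changed genes compare with at most 0 in the other splits of the 6 libraries, where 1 of 10 splits, the real one, gave as many. Every other split puts both genotypes in both groups, which widens the spread within groups, so counts near 0 were to be expected there. The 10 splits are also too few for a share under 0.05.

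The 137 genes changed at least 4-fold spread over the genome. DNA carried along with the mutation does not account for them as a whole, since 3 of 136 apart from Galt, 2.21% (95% exact interval 0.457 to 6.31), lie within 20 Mb of Galt. Strain differences elsewhere in the genome may account for part: with H2-Ea-ps, seen before this class was chosen, left out, 2 of 8 polymorphic pseudogenes (Atp10d, Cd1d2; Atp10d alone without wildtype replicate 1) changed at least 4-fold against 134 of 16948 other genes, an odds ratio of 41.8 (Fisher's exact p = 0.00173). Pseudogenes were over-represented with an odds ratio of 13.2 (48 of 708 against 89 of 16249, Fisher's exact p = 9.83e-32). Reads moving between near-identical copies could account for them, but so could strain differences in the copies. The odds ratio does not tell these explanations apart. Both stay open, and an effect of the missing enzyme cannot be separated from strain where wildtype and GalTKO mice came from different stocks, which the labels do not say.

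The lower cholesterol genes were tested against luteal content, because luteal cells use much cholesterol. The luteal score was 7.78, 7.73 and 7.48 (mean log2 CPM of 12 markers) in wildtype replicates 1 to 3 and 7.65, 7.01 and 7.81 in GalTKO replicates 1 to 3. GC content and transcript length do not account for the fall as a whole, since the list median was -0.948 after a trend with them was removed. With the luteal score in the fit the median was -0.982, but the luteal list's own median went from -0.366 to -0.589, so that fit does not test luteal content and a smaller share of luteal cells stays open. Diet intake, estrous stage and strain were not tested.

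The lower macrophage and endothelial genes may reflect fewer such cells or lower expression in them, which whole-tissue counts do not separate. The mean log2 fold change of smooth muscle and pericyte genes lay 0.35 above that of endothelial genes (permutation test over genes, which are not independent, p = 0.00098). These genes went both ways, 8 positive and 6 negative, and without GalTKO replicate 2 their median was -0.159, so a loss of vessel and stromal tissue as a whole stays open. The lower macrophage list does not rest on H2-Aa, H2-Ab1, H2-Eb1 and Cd74 alone. Without these 4 genes its median was -0.63 and 16 of 21 members passed over the list alone. Since 20 of all 25 members passed, leaving out any 4 had to leave at least 16. That count is therefore no test of strain alleles. Strain effects, estrous stage and blood content stay open.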
